A study of Pteromalus puparum with 9 samples.

How the data were processed

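RNA from the salivary gland duct, the salivary gland reservoir and the carcass of wild-type Pteromalus puparum was measured by bulk, strand-specific, paired-end RNA sequencing on an Illumina platform after TRIzol extraction, per the labels' protocols. Groups and replicate numbers were taken from the labels, giving 3 libraries per tissue and 9 in all. Transcripts were quantified with Salmon 1.9, per the submitters' processing notes. The reference transcripts, index settings and genome build are not given in the sources used here.

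The authors deposited a table of estimated counts per transcript model, given as whole numbers and not normalized, and rounding here changed none of them. The authors also deposited a table of TPM, an abundance corrected for transcript length, in which 8 of the 9 columns sum to 1000000. The TPM column of reservoir replicate 2 sums to 2000000 and equals, in 99.95% of models within 2e-06, the sum of the columns of duct replicate 3 and reservoir replicate 1, so the main results do not use it, it enters only the alternatives that take the column as deposited, and mean TPM values of the reservoir rest on 2 libraries. Count columns of all 9 libraries were used. Total counts were 18690598, 22220312 and 20259970 in duct replicates 1 to 3, 18814337, 19739796 and 22640711 in reservoir replicates 1 to 3, and 21826029, 20220473 and 22061863 in carcass replicates 1 to 3. A count of 0 in 1 library allows a level of up to 0.0942 to 0.207 CPM, from 3 counts of the TMM-scaled total.

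Replicates were compared before they were averaged. Log CPM values of replicates correlated at 0.84 to 0.85 within the duct, 0.839 to 0.853 within the reservoir and 0.792 to 0.842 within the carcass, and no pair of libraries agreed within sampling noise.

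Counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr with the tissues as groups, which kept 21287 of 40026 models and at least 99.662% of the counts of each library, TMM scaling, and a quasi-likelihood F test with 1 coefficient per tissue fitted to all 9 libraries. TMM factors were 0.9678 to 1.071 in the duct, 0.7427 to 0.8229 in the reservoir and 1.05 to 1.58 in the carcass. A model was called at a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 fold change of at least 1. The common biological coefficient of variation was 0.771 over models and 0.367 over ID stems. Standard errors of log2 fold changes were derived from the F statistic. The 3 pairwise comparisons, the sets of models called in 2 of them, the share of counts in the 10 most abundant models and the correlation of the comparisons against the carcass were fixed, with their tests and thresholds, before the data were examined. One value per library was compared by exact permutation tests, two-sided. Tests of isoform usage per ID stem (voom and diffSplice in limma 3.58.1), the counts summed per ID stem and the shares of counts per ID class were added after the data were seen, and diffSplice was chosen over edgeR's diffSpliceDGE after the test on simulated data. The simulated results given here are those of diffSplice alone, so they do not compare the tools. Isoform usage in the real data was also tested with diffSpliceDGE, Simes p values per stem, a minimum isoform share and the replicate block. Stem counts from those settings are not given here.

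Named models followed a rule fixed with these tests. With no source used here that pairs IDs with gene names, it takes per comparison the 2 models that rose and the 2 that fell most, among called models whose 3 libraries in one tissue all lie above the 3 in the other and whose mean in the higher tissue is at least 50 CPM. For a model without a count in one tissue the fold is a lower bound, computed with 3 counts over the group. Gene lists and cell type marker lists had been fixed by gene description, and they were not run for the same reason. The meaning of the prefixes in the IDs is not given in the sources used here. Isoforms of an ID stem can share reads, so counts of single isoforms can depend on how Salmon divides them, and values of stems are given beside those of models.

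The scripts were tested on simulated data drawn from the means and library sizes of the real libraries, with 50 models changed per fold size in each comparison. Changes were rises and falls in equal number. Few models were changed, where the real comparisons called 26.5%, 31.2% and 9.06% of tested models, and the adjustment is stricter when few models change. A 2-fold change also lies at the fold minimum itself. The recoveries below are therefore not those of the real comparisons. The edgeR test recovered 0%, 14%, 24% and 50% of models changed by 2, 4, 8 and 16 times for duct against carcass (19961 models), 0%, 30%, 30% and 48% for reservoir against carcass (19871 models) and 0%, 24%, 38% and 52% for reservoir against duct (19910 models). False calls made up 0%, 0% and 1.72% of the calls. The isoform test recovered 63.5%, 70% and 62% of 200 changed stems in the 3 comparisons, with 3.05%, 1.41% and 0.8% false calls. In each changed stem the 2 leading models traded places entirely in 1 tissue. Only stems whose leading model was abundant and well above the next were changed. Smaller changes of usage were not simulated.

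The alternatives tried were DESeq2 size factors, library size alone and upper-quartile scaling, no filter on low counts and a minimum of 10 CPM in 3 libraries, the DESeq2 1.42.0 Wald test, limma-trend on log2(TPM + 1), no fold minimum and edgeR's glmTreat against a fold of 2, a fit with the compared tissues alone, the replicate number as a block, and each library left out in turn. Alternatives added after the data were seen were log2(TPM + 0.1) for the counts of called models (planned for named models), 9 libraries with the TPM column of reservoir replicate 2 rebuilt from its counts or as deposited, counts summed per ID stem, and models without unstable zeros.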

Results

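The salivary glands of Pteromalus puparum, a parasitoid wasp that develops inside butterfly pupae, were profiled by bulk RNA sequencing of the gland duct, the gland reservoir and the carcass, a term the labels do not define further. Each of the 3 tissues was represented by 3 wild-type libraries labelled as biological replicates and as a single batch. The libraries held between 18690598 and 22640711 estimated counts, spread over 40026 transcript models, of which 9367 had no count in any library. Models are given by the IDs of the deposited tables, which do not pair them with gene names. An ID without its isoform number is called an ID stem here and stands in for a gene only as a proxy, since stems of different ID classes may overlap in 1 locus. The labels do not say whether the replicates came from separate animals or separate pools, so the p-values measure the spread between these samples. Intervals and detection floors cover counting error only.

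The salivary duct differed from the carcass in 5650 of 21287 tested models, 26.5% of them, with 2455 higher and 3195 lower in the duct. With counts summed per ID stem, 4651 of 12143 stems were called, 1977 higher and 2674 lower. Differences were often very large: 563 models were at least 64-fold higher and 1074 at least 64-fold lower in the fitted values. Under the rule for named models, PB.144.76x and PB.144.64x showed the largest rises. PB.144.76x stood at 193 ± 25 CPM (TMM-scaled count per 1000000, SD, n = 3) in the duct with no count in the carcass. With 3 counts over the carcass group as the floor it was at least 5270-fold higher. PB.144.64x stood at 94.3 ± 30.4 CPM, at least 2570-fold higher. Both belong to an ID stem of 73 models whose summed counts rose far less, by a log2 fold change of 2.33 ± 0.44 (SE; edgeR adjusted p = 0.00257). The largest falls were those of PB.6442.30x, at 38600 ± 36600 CPM in the carcass and at least 792000-fold lower in the duct, and of PB.414.25x, at 7780 ± 10100 CPM in the carcass and at least 160000-fold lower, neither with any duct count. Carcass replicate 3 carried much of both levels: without it PB.6442.30x stood at 17900 CPM and was at least 368000-fold lower, and PB.414.25x stood at 2040 CPM and was at least 42000-fold lower. Carcass replicate 2 held 13 counts of PB.414.25x and gave a bound of 240000 when left out. The ID stems of PB.6442.30x and PB.414.25x, of 10 and 6 models, fell too, with log2 fold changes of -11.88 ± 1.51 (edgeR adjusted p = 0.000296) and -9.12 ± 0.41 (edgeR adjusted p = 3.92e-06).

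These calls came from edgeR's quasi-likelihood test, with Benjamini-Hochberg adjusted p values of 0.0272 for PB.144.76x, 0.0136 for PB.144.64x, 0.00587 for PB.6442.30x and 0.0269 for PB.414.25x. The calls of PB.144.76x and PB.414.25x were lost in most fits that left out 1 library: the edgeR adjusted p lay at 0.0522 to 0.0634 for PB.144.76x without duct replicate 1, 2 or 3, reservoir replicate 1, or carcass replicate 1, 2 or 3, and at 0.052 to 0.0915 for PB.414.25x without any 1 library other than carcass replicate 2. In those fits the log2 fold change was 14.94 to 15.11 for PB.144.76x and -20.59 to -18.39 for PB.414.25x, against 15 and -20.34 with all 9 libraries. The share of called models that were higher in the duct was 43.5% after TMM scaling, 31.9% when libraries were scaled by size alone and 20.5% with limma on log2(TPM + 1). Without carcass replicate 1 edgeR called 2438 higher and 2419 lower.

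The salivary reservoir differed from the carcass in 6640 models, 31.2% of those tested, with 2591 higher and 4049 lower in the reservoir. Summed per ID stem, 5156 of 12143 stems were called, 1817 higher and 3339 lower. The largest rises were those of PB.3637.1 and PB.8432.1. PB.3637.1, the 1 model of its ID stem, reached 792 ± 66.3 CPM in the reservoir and 49.1 ± 10.6 CPM in the duct and had no count in the carcass, so that it was at least 21600-fold higher in the reservoir than in the carcass. PB.8432.1 had 159 ± 22.4 CPM in the reservoir and no count in the duct or carcass libraries, at least 4330-fold higher than in the carcass, and its stem of 3 models rose as well, by 5.29 ± 0.33 on the log2 scale (edgeR adjusted p = 6.69e-06). The largest falls were those of PB.6442.30x, at least 613000-fold lower in the reservoir, and PB.414.13x, which had 2520 ± 3630 CPM in the carcass and was at least 40100-fold lower. Without carcass replicate 3 the carcass levels were 17900 CPM for PB.6442.30x and 442 CPM for PB.414.13x, which lowered the bounds to 285000 and 7030. The stems of these models also fell, with log2 fold changes of -8.42 ± 1.33 (edgeR adjusted p = 0.000814) and -5.21 ± 0.35 (edgeR adjusted p = 8.97e-06).

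The edgeR adjusted p was 1.68e-05 for PB.3637.1, 0.000151 for PB.8432.1, 0.00506 for PB.6442.30x and 0.0379 for PB.414.13x. The call of PB.414.13x was lost, at edgeR adjusted p values of 0.0632 to 0.0887, without reservoir replicate 1, 2 or 3 or carcass replicate 1 or 3. Of all called models 39% were higher in the reservoir after TMM scaling, 19.6% when libraries were scaled by size alone and 12.5% with limma on log2(TPM + 1).

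Duct and reservoir shared much of their difference from the carcass. A set of 1809 models was higher in both gland parts, and these models held 64.2% ± 0.638 of the counts in the duct and 80.3% ± 0.526 in the reservoir but 3.92% ± 0.553 in the carcass (SD, n = 3 each). A set of 2539 models was lower in both gland parts and held 1.19% ± 0.0284 of duct counts, 0.983% ± 0.14 of reservoir counts and 62.9% ± 5.61 of carcass counts. The balance of these sets depended on the processing, with 1268 higher and 3483 lower in both when libraries were scaled by size alone. Limma on log2(TPM + 1) gave 798 and 5434, and edgeR gave 1122 and 1337 among models with at least 10 CPM in 3 libraries. Independent lists of these lengths would have shared 299 higher and 608 lower models, a number that leaves out the shared carcass libraries. Because the simulations described next leave out the effects, their 0 shared models in either direction do not measure the sharing. Across the tested models, which are not independent replicates, the log2 fold changes of the 2 gland parts against the carcass correlated with Pearson r = 0.733 and Spearman rho = 0.7, and 78.8% of models had the same sign. Simulations with unchanged groups drew all 9 libraries anew from the mean levels of the carcass libraries. They gave a mean r of 0.501, rho of 0.449 and 66.6% with the same sign over 20 simulations. Models without a carcass count, PB.3637.1 among them, were drawn at 0 and so entered only the observed values. Observed and simulated values therefore cover different models. The covariance was 8.34, against 0.739 in the simulations, a difference of 7.6. The simulated comparisons already shared a carcass group, so the excess is what lies beyond that sharing under their setting. The 3 real carcass libraries were too few to be divided into parts of at least 2, so a larger part from the shared controls is not excluded.

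**Figure D1:**
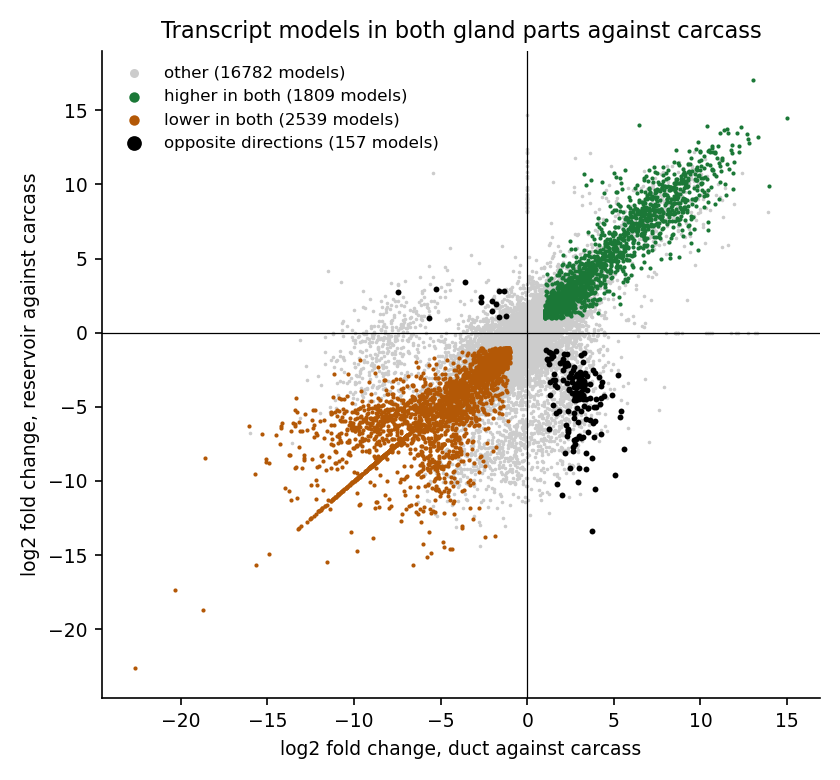
Log2 fold change of the duct against the carcass (x axis) and of the reservoir against the carcass (y axis), 1 point per tested transcript model (edgeR, 3 libraries per tissue), coloured by the calls in both comparisons. The 1809 models higher in both gland parts and the 2539 lower in both lie along the diagonal; fold changes of models with no count in 1 tissue depend on the prior count.

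The models with the most gland counts were Ppup084370.1 and Ppup084360.1, which were chosen after their values were seen. Ppup084370.1 took 13.2% ± 0.745 of duct counts, 15.1% ± 1.61 of reservoir counts and 0.653% ± 0.194 of carcass counts, and Ppup084360.1 took 10.2% ± 1.06, 12.5% ± 0.753 and 0.624% ± 0.238 (SD, n = 3 each). In the authors' TPM, which corrects for length, the order turned: Ppup084360.1 averaged 42400 in the duct and 49100 in the reservoir, and Ppup084370.1 averaged 23300 and 25900 (n = 3 in the duct, n = 2 in the reservoir). By counts the pair together made up 23.5% ± 0.834 of the duct and 27.6% ± 1.64 of the reservoir libraries, against 1.28% ± 0.423 of the carcass libraries. Ppup084370.1 was higher than in the carcass by 4.59 ± 0.77 in the duct (log2, SE; edgeR adjusted p = 0.00348) and by 5.16 ± 0.8 in the reservoir (edgeR adjusted p = 0.00191). Ppup084360.1 was higher by 4.29 ± 0.76 (edgeR adjusted p = 0.00446) and 4.95 ± 0.79 (edgeR adjusted p = 0.00219). Between reservoir and duct neither passed the test, with log2 fold changes of 0.56 ± 0.67 (edgeR adjusted p = 0.707) for Ppup084370.1 and 0.67 ± 0.67 (edgeR adjusted p = 0.637) for Ppup084360.1.

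**Figure D2:**
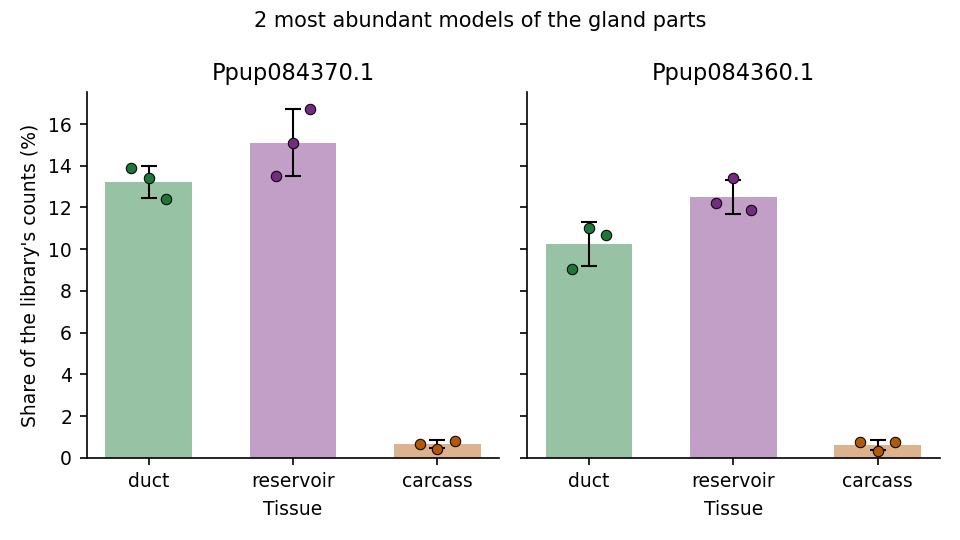
Percent of each library's counts (y axis) in Ppup084370.1 and Ppup084360.1, with 1 point per library, bars at the mean of the 3 libraries of a tissue and error bars of 1 SD. Means lie at 13.2% and 10.2% in the duct, 15.1% and 12.5% in the reservoir and 0.653% and 0.624% in the carcass.

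Reservoir and duct differed from each other in 1929 models, 9.06% of those tested, with 708 higher and 1221 lower in the reservoir. Over ID stems the test called more, 2079 of 12143, with 758 higher and 1321 lower. The largest rises were those of PB.2543.35x, at 438 ± 210 CPM in the reservoir, and PB.144.103x, at 312 ± 164 CPM, which had no count in the duct and were at least 9000-fold and at least 6410-fold higher. The summed counts of their ID stems, of 40 and 73 models, did not pass the test, with log2 fold changes of 2.14 ± 0.79 (edgeR adjusted p = 0.0859) and 0.28 ± 0.42 (edgeR adjusted p = 0.688). The largest falls were those of PB.6097.12x and PB.1473.1x. PB.6097.12x had 843 ± 273 CPM in the duct and no count in the reservoir, at least 13400-fold lower, while its stem of 3 models differed by -1.52 ± 0.5 (log2; edgeR adjusted p = 0.0577). PB.1473.1x, the 1 model of its stem, had 46005 counts over the 3 duct libraries (726 ± 747 CPM) and 1 count over the reservoir libraries, a ratio of 35600 with a 95% counting interval of 6390 to 1410000. Duct replicate 2 held 33954 of these counts, and without it the duct level was 299 CPM and the ratio 14300.

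The edgeR adjusted p was 0.0101 for PB.2543.35x, 0.0427 for PB.144.103x, 0.00182 for PB.6097.12x and 0.00921 for PB.1473.1x. The call of PB.144.103x was lost without any 1 library other than carcass replicate 1 (edgeR adjusted p of 0.0614 to 0.102), and that of PB.1473.1x without reservoir replicate 2 (0.0636). DESeq2 called 3207 models and edgeR's test against a fold of 2 called 1056. Of the called models 36.7% were higher in the reservoir after TMM scaling, 20.3% when libraries were scaled by size alone and 20.6% with limma on log2(TPM + 1). Scaling by size alone moved the median log2 fold change of all tested models by -0.351 for duct against carcass, -0.724 for reservoir against carcass and -0.368 for reservoir against duct, and upper-quartile scaling moved that of reservoir against carcass by 0.127.

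Smaller sets of models peaked in 1 gland part. The 378 models higher in the duct than in both other tissues held 5.61% ± 0.309 of duct counts, 0.518% ± 0.0203 of reservoir counts and 0.998% ± 0.461 of carcass counts. The 353 models higher in the reservoir than in both other tissues held 12.8% ± 1.15 of reservoir counts, 4.42% ± 0.414 of duct counts and 0.39% ± 0.0654 of carcass counts (SD, n = 3 each). Of these 353, 179 were also higher in the duct than in the carcass, and of the 378, 34 were also higher in the reservoir than in the carcass. The numbers depended on single libraries: 196 duct-high models were called without duct replicate 2 and 182 without duct replicate 3. There were 216, 204 and 200 reservoir-high models without duct replicate 2, reservoir replicate 1 and reservoir replicate 2. DESeq2 gave 664 duct-high and 593 reservoir-high models, and edgeR's test against a fold of 2 gave 150 and 137. Scaling by size alone gave 370 and 194, and limma on log2(TPM + 1) gave 527 and 235.

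The number of models above a fixed unscaled CPM differed between the tissues, while the share of counts in the leading models did not pass its test. The 10 most abundant models took 36.9% ± 1.08 of the counts in the duct, 46% ± 1.14 in the reservoir and 44.5% ± 6.17 in the carcass (SD, n = 3 each). Duct and reservoir had 7 of these 10 models in common, and neither had any in common with the carcass. The number of models with at least 1 CPM, without TMM scaling, was 15100 ± 333 in the duct, 13800 ± 198 in the reservoir and 17000 ± 754 in the carcass, which differed in an exact permutation test over every assignment of the 9 libraries to the 3 tissues (p = 0.00357, the smallest that test can give). A library with a lower TMM factor meets a higher cutoff on the TMM scale. These factors were 0.9678 to 1.071 in the duct, 0.7427 to 0.8229 in the reservoir and 1.05 to 1.58 in the carcass. How much of the difference in number comes from the scaling was not tested. The share of the 10 most abundant models did not pass the exact permutation test (exact p = 0.0536), although it did without carcass replicate 2 (exact p = 0.0286) or carcass replicate 3 (exact p = 0.00357). The numbers of models that together held 50% of the counts were 38 ± 4.58 in the duct, 14.7 ± 1.53 in the reservoir and 32 ± 27.2 in the carcass (exact p = 0.229), and for any pair of tissues 3 libraries against 3 allow no exact two-sided p under 0.1.

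**Figure D3:**
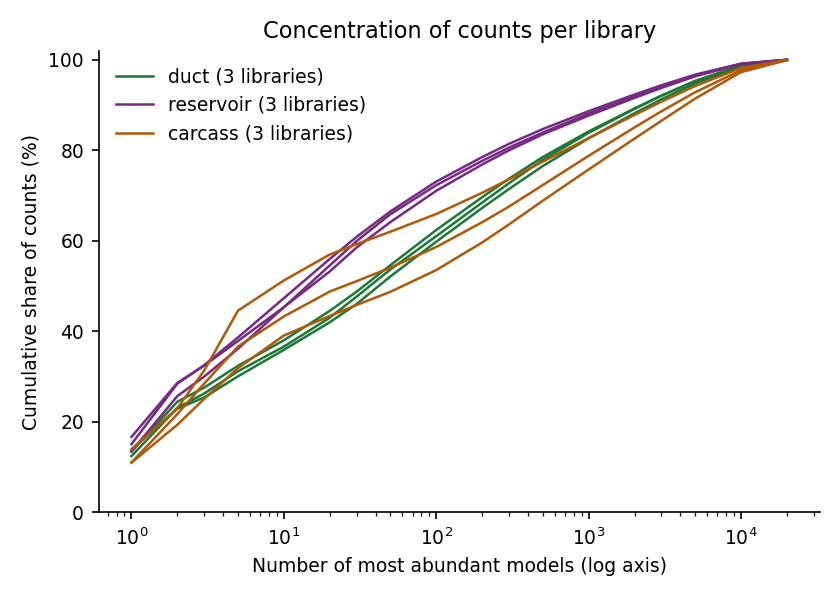
Cumulative percent of counts (y axis) against the number of most abundant transcript models summed in each library (x axis, log scale), 1 line per library, coloured by tissue. At 10 models the lines average 36.9% in the duct, 46% in the reservoir and 44.5% in the carcass.

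Tissues also used different isoforms of the same ID stem. Among 4152 stems with at least 2 tested models, isoform usage differed in 639 between duct and carcass (15.4%), in 677 between reservoir and carcass (16.3%) and in 221 between reservoir and duct (5.32%). In 144, 168 and 46 of these stems, respectively, the leading model was the same in the 3 libraries of a tissue and differed between the tissues. These numbers set no minimum count, so libraries without a count of a stem were not left out. In 98, 111 and 35 of these stems every library of the compared tissues held at least 100 counts of the stem. PB.2614, a stem of 7 models chosen after its values were seen, was read as PB.2614.8 in the glands, at 98.6% ± 1.02 of the stem's counts in the duct and 99.1% ± 0.103 in the reservoir against 3.54% ± 1.37 in the carcass. PB.2614.6 took 79.5% ± 7.36 in the carcass, 0.00902% in the duct and 0.0206% in the reservoir (SD, n = 3; limma adjusted p = 7.89e-12 for duct against carcass and 8.08e-14 for reservoir against carcass). The test was limma's diffSplice F test on voom values with Benjamini-Hochberg adjustment. Between reservoir and duct the number of stems was 107 without duct replicate 2, 115 without duct replicate 3, and 103, 101 and 126 without reservoir replicates 1, 2 and 3. Stem totals did not pass the test in 376, 381 and 167 of the stems with changed usage in the 3 comparisons.

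**Figure D4:**
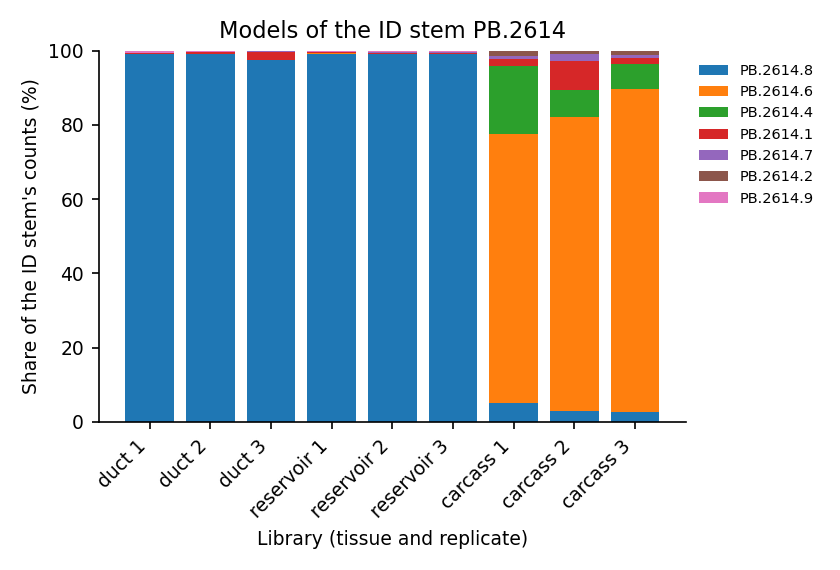
Percent of the counts of ID stem PB.2614 (y axis) in each of its 7 models, stacked to 100% in 1 bar for each of the 9 libraries (x axis, tissue and replicate). PB.2614.8 averages 98.6% in the duct and 99.1% in the reservoir, and PB.2614.6 averages 79.5% in the carcass.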

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

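The tests of the TPM column were chosen only after the result was seen.

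In the duct 144 models were called above the carcass that the reservoir comparison called below it, and reservoir and duct differed from each other in all 144 (edgeR adjusted p under 0.05). That contrast is the difference of the 2 that chose these models, in the same fit, so it is no separate evidence. Their number was 83, 70 and 69 without duct replicates 1, 2 and 3 and 81 and 76 without carcass replicates 2 and 3, with a range of 69 to 181 over the 9 libraries left out in turn. The opposite pattern, above the carcass in the reservoir and below it in the duct, held for 13 models, and for 8 without reservoir replicate 1, reservoir replicate 2 or carcass replicate 3. The 144 models held 2.5% ± 0.267 of duct counts, 0.0361% ± 0.0104 of reservoir counts and 0.451% ± 0.234 of carcass counts, and over ID stems the numbers were 225 and 22.

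The deposited TPM column of reservoir replicate 2 was above 0 for 4855 models that had no count in that library, and at 0 for 1674 models that had one. The count column does not appear to be the wrong one, since its lowest correlation with another reservoir library exceeded its highest with a duct library by 0.113 (log CPM). The column equalled the sum of the TPM columns of duct replicate 3 and reservoir replicate 1 in 99.95% of models within 2e-06, against 41.8% for the next pair of columns. Used as deposited, limma-trend called 257 models between reservoir and duct, all higher in the reservoir, and 0 lower (677 at an unadjusted p under 0.05, and 1221 lower with edgeR on the counts), and with the column rebuilt from the counts it called 1992. The column is therefore taken as that sum, and how it came to be deposited is not given in the sources used here.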

How the results depend on the processing

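The tests per ID stem, of isoform usage, of the counts of models with log2(TPM + 0.1), and with the TPM of reservoir replicate 2 as deposited or rebuilt were chosen only after the data were seen. No named model changed direction under any alternative run, but the balance of calls turned in 2 cases: from 1221 lower and 708 higher to 0 lower and 257 higher between reservoir and duct with the TPM column as deposited, and from 3195 lower and 2455 higher to 2419 lower and 2438 higher between duct and carcass without carcass replicate 1. Of the main results, 92 values under other settings and 90 with a library left out stayed the same (within 1.5 times a count, within 1 SD of a value, or on the same side of a threshold), 34 and 16 moved, and 2 passed a threshold they had missed. Duct-high and reservoir-high models are those higher there than in both other tissues. Where no reason is named, the cause was not tested.

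With at least 10 CPM in 3 libraries, which tests fewer models, the counts were 3063 (duct against carcass), 3561 (reservoir against carcass), 1122 (higher in both gland parts) and 1337 (lower in both). Scaling by library size alone gave 194 reservoir-high models. The DESeq2 Wald test gave 3207 between reservoir and duct, 664 duct-high and 593 reservoir-high models, with 349 adjusted p values missing per comparison. The stricter glmTreat gave 1056 between reservoir and duct, 1189 higher in both, 150 duct-high and 137 reservoir-high. On log2(TPM + 1) in 8 libraries limma-trend gave 798 higher in both, 5434 lower in both and 235 reservoir-high; with the rebuilt column 812, 5550 and 589 duct-high; with the column as deposited 890, 4838, 257 between reservoir and duct, 179 reservoir-high and 0 duct-high (201 at an unadjusted p under 0.05, 378 with edgeR). On log2(TPM + 0.1) it gave 9766, 11398, 1056 higher in both, 7079 lower in both and 214 reservoir-high.

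Deviations of same-numbered libraries correlated at -0.13 to 0.039 over 9 pairs, against -0.054 to 0.14 for different numbers, so not every library correlated best with its own number and replicate numbers were not taken as pairs. The replicate block gave 1130 between reservoir and duct, 1686 lower in both and 183 reservoir-high, 4134 and 5177 against the carcass, and edgeR adjusted p values of 0.0896 for PB.144.76x, 0.0536 for PB.6442.30x in the duct, 0.0549 for PB.2543.35x and 0.159 for PB.144.103x.

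With a library left out, duct-high models ranged from 182 to 519 and reservoir-high from 200 to 381. Stems with changed isoform usage between reservoir and duct ranged from 101 to 281. The correlation of the comparisons against the carcass ranged from 0.682 to 0.75. That correlation was 0.831 on log2(TPM + 1), 0.687 without a filter and 0.789 with a prior count of 5. The share of the 10 most abundant models, reservoir minus duct, ranged from 8.49 to 9.74 points with a library left out. Over the 3 tissues, not between reservoir and duct, the exact p of that share was 0.0286 without carcass replicate 2 and 0.00357 without carcass replicate 3. Beyond the settings named in the report, edgeR adjusted p rose to 0.0509 for PB.144.103x without a filter, and to 0.057 for PB.414.13x and 0.0734 for PB.144.103x under glmTreat, and PB.414.25x reached 0.0808 with the compared tissues alone. Gene list tests and sums per gene were not run, since no source used here pairs IDs with genes. Counts set the floor at 0.0942 to 0.207 CPM per library, and changes of 2-fold, at the fold minimum itself, were recovered in 0% of simulated models. Few models were changed in that simulation, so this is not the recovery in the real comparisons.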

Other observations

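The tests of unstable zeros and of carried-over RNA, and the shares per ID class, were chosen only after the data were seen.

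ID classes took different shares of the tissues' counts. Models with the prefix PB and no final x held 49.2% ± 6.3 of carcass counts, 30.9% ± 1.46 of duct counts and 25.8% ± 0.652 of reservoir counts, and PB models with a final x held 21.6% ± 1.86, 29.5% ± 0.33 and 29.2% ± 0.684 (SD, n = 3 each). Ppup models held 26.7% ± 5.19, 33.2% ± 1.29 and 38.2% ± 0.969, and MSTRG models 2.25% ± 0.416, 6.17% ± 0.143 and 6.58% ± 0.321, in the same order of tissues. MSTRGCarcass models held 0.101%, 0.0434% and 0.0355%, and MSTRGVenom models 0.178%, 0.139% and 0.103%, so that the class with Venom in its name was lowest in the reservoir. Exact permutation tests over the 3 tissues, adjusted over 6 classes, gave p = 0.00714 for PB, Ppup and MSTRGCarcass, 0.00857 for MSTRG and MSTRGVenom and 0.025 for PB with a final x. In TPM the Ppup models stood 4.66 points higher in the glands than in the carcass. The exact test of their TPM share over the 3 tissues, not of glands against carcass, gave p = 0.293. MSTRGVenom stood at an exact p of 0.0536 over the 3 tissues without reservoir replicate 1 or reservoir replicate 2. With the 23 models left out that were among the 10 most abundant of any tissue, Ppup models held 3.09% ± 1.35, 13% ± 1.2 and 12.4% ± 1.06 of the remaining counts (carcass, duct, reservoir) and MSTRG models 3.81% ± 0.409, 6.14% ± 0.461 and 4.78% ± 0.924, so that the reservoir no longer stood above the duct in either class (exact p over the 3 tissues 0.0214 for each). In the reservoir against the carcass 273 Ppup models were called lower and 148 higher and 407 MSTRG models lower and 153 higher, where all tested models gave 4049 and 2591. Neither class passed limma's camera test against the other models (adjusted p = 0.0772 for each, and adjusted p = 0.232 for Ppup and 0.115 for MSTRG with an estimated correlation). In the duct against the carcass PB models with a final x passed it as higher (adjusted p = 0.0495, and adjusted p = 0.04 with an estimated correlation), and the other PB models were lower at an adjusted p = 0.17, or adjusted p = 0.04 with an estimated correlation. What the prefixes stand for is not given in the sources used here.

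In 935 instances, over 837 models, a model had no count in 1 library while the other 2 of its tissue held 100 or more each: 474 in the carcass, 283 in the duct and 178 in the reservoir. The named models PB.144.76x and PB.144.103x were among them, each in the tissue outside the comparison that named it. PB.144.76x had 1342, 0 and 5663 counts in reservoir replicates 1 to 3. PB.144.103x had 0, 423 and 899 in carcass replicates 1 to 3. Assignment of the reads to another model of the same ID stem may contribute, since 95.7% of instances lay in stems of at least 2 models, against 65.6% of 12702 comparable models. In 84.8% of instances the stem total in the library at 0 was not more than halved against the lower of the other 2 libraries. That share cannot decide the cause, since a minor model at 0 barely moves the total of its stem whatever the cause. It was not computed for comparable models. Totals of 18690598 to 22640711 argue against 1 library of low depth. From the other libraries and the totals alone, the library at 0 would have held at least 83.9 counts in every instance. A count of 0 allows 3. Since the other 2 libraries had to hold 100 or more, these totals fix that result, and it adds nothing to them. The library with the lowest total still held the most instances in 3 of 3 tissues. Instances fell to replicates 1, 2 and 3 as 81, 220 and 173 in the carcass, 104, 76 and 103 in the duct and 69, 55 and 54 in the reservoir. A biological difference between replicates was not tested.

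Stems called higher in the carcass than in both gland parts, or the reverse, kept a low level in the other tissue; those with a mean of at least 100 CPM where they were high were examined. The 264 carcass-high stems stood at a median of 1.73% to 3.04% of their carcass level in the gland libraries, and the 336 gland-high stems at 3.26% to 5.73% of their gland level in the carcass libraries. Carcass RNA or reads carried over in 1 proportion would give every stem nearly the same ratio, but the interquartile range of the log2 ratio was at least 2.95 in the gland libraries, against at most 0.603 among carcass replicates. For carry-over from gland to carcass it was at least 4.72, against at most 0.477 among gland replicates. Carry-over in 1 proportion is therefore argued against as the whole source, a smaller part of it stays open, and low expression of these stems in the other tissue was not tested.

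Other splits of the samples were set against the real one. For 3 libraries against 3, 10 splits are too few for a share under 0.05: the real split gave 5650 models for duct against carcass, 6640 for reservoir against carcass and 1929 for reservoir against duct, with at most 5, 1 and 4 in any other split, and 639, 677 and 221 stems with changed isoform usage, with at most 55, 14 and 17. Of 100 splits of the 9 libraries, the real one included, only the real one gave as many models higher, or lower, in both gland parts. It gave 1809 higher (highest other 1654) and 2539 lower (highest other 2089). The highest other splits kept the 3 carcass libraries together. The real split with duct and reservoir labels exchanged would give the same sets and was not among the splits drawn. The share of 1 in 100 speaks to the labels of the 9 libraries as a whole. It does not show that chance is excluded for either comparison with the carcass, for which 10 splits are too few. For the 378 duct-high and 353 reservoir-high models 2 of 100 splits, the real one and 1 other, gave as many, with 2060 and 2050 in the highest other split. The share is under 0.05, but nearly all of these splits mix carcass with gland libraries, so it does not show that chance is excluded between duct and reservoir, for which the 10 splits are too few. In the highest other splits the carcass libraries carried the duct or the reservoir label, which points to the difference between carcass and gland as the largest structure of the samples.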
